A study of Mus musculus with 6 samples.

How the data were processed

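RNA was measured in Ter119-positive erythroid cells from the spleens of mice with sickle cell disease, 3 libraries wild type for Nrf2 (WT) and 3 Nrf2 knockout (KO), from animals of 2 to 3 months on a mixed background of the B6 and 129P2 strains. Ter119 is a surface marker of erythroid cells. Per the labels' protocols, RNA was purified with a PureLink kit and 1 ug went into an Illumina TruSeq version 2 library, a kit that does not mark strand. The authors deposited 1 table of whole-number read counts per gene symbol. The submitters' processing notes name STAR 2.5, HTSeq, DESeq2 and the mouse build mm10, without giving the role of each. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical copies cannot be told apart.

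The deposited count table has 35275 lines. In 27 of them the gene name had been turned into a date. These held 0.340% to 0.383% of the reads of a library and were left out. Another 122 lines shared 52 symbols and were summed by symbol, which left 35178 symbols, of which 13498 had no read in any library. Library totals ran from 16420054 to 21790983 reads, and reads of the mitochondrial genome made up 1.71% to 3.90%. Positions, lengths and GC content came from GENCODE M21, built on the same mouse assembly, and were found for 13545 of the 13721 genes tested.

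Groups and replicates were taken from the labels. Nothing in the labels says whether each library came from its own animal, so p-values measure the spread between these libraries, which may be technical. Before averaging, libraries were compared by a chi-square over genes with at least 10 reads; the closest pair differed by 22.1 per gene, so no pair was within sampling noise. The labels give no sex, and Xist and chromosome Y reads were counted in each library.

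Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling, robust dispersions and the quasi-likelihood F test of KO against WT with no covariate. An adjusted p (Benjamini-Hochberg) under 0.05 counted as a call. Levels are CPM, counts divided by TMM-scaled library sizes, given as mean ± SD over the libraries of a group. Fold changes are log2 of KO over WT with a prior count of 0.125, given with a standard error (SE). The biological coefficient of variation was 0.223. With 3 libraries against 3, an exact permutation test of 1 gene cannot give a two-sided p below 0.1.

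Gene lists, the rule for named genes and the tests were fixed before the data were examined. There were 46 lists of pathways, gene families and markers of other spleen and blood cells. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and adjusted over the 46 lists, and again with an estimated correlation and with fry. The members of each list were also adjusted over the list alone. Lists share members, so their results are not independent. The named genes are Nfe2l2 and 1 other gene, which is not reported here; up to 12 raised and 12 lowered genes with the largest changes past the threshold, with an average log2 CPM of at least 1, no overlap between the groups and no predicted or clone-named models; up to 4 tested members of each list with the smallest p; and the 5 genes with the highest mean count in each group.

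The tests were checked on data simulated from the means, dispersions and depths of these libraries, 3 times, with 200 genes changed. Over 13487 to 13503 genes, edgeR recovered 64.5% of the genes changed by 1 log2 unit and 94.7% of those changed by 2, and 7.31% of its calls were false. DESeq2 recovered 71.7% and 95.3% with 16.0% false over 13721 genes, and limma-voom had 7.47% false. A planted list of 25 genes at a log2 change of -0.5 was called in 3 of 3 simulations with the preset correlation and in 0 with the estimated one. Of 120 unchanged lists, 0 were called by either. Genes were simulated independently and lists drawn at random, so this does not check camera where members move together. The estimated correlation reached 0.900 in the lists tested here. With the preset correlation, splits of the libraries into 3 and 3 that mix WT and KO gave 5 to 17 list calls.

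The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), DESeq2 1.42.0 and limma-voom, no filter and a stricter one of 1 CPM in 3 libraries, the 10 most abundant genes and the globins left out, cell marker and antigen receptor genes left out, a test against a fold of 1.5, each library left out in turn, and the replicate number as a block. KO replicate 3 alone against WT, genes on X and Y left out, and the removal of trends with GC content and transcript length were added after the data were seen.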

Results

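Transcript levels of splenic Ter119-positive erythroid cells were compared between sickle cell disease mice with and without Nrf2. Nrf2, encoded by Nfe2l2, is the transcription factor that drives antioxidant response genes, and the series title ties it to L-2-hydroxyglutarate and to ferroptosis, an iron-dependent form of cell death. Each group had 3 libraries. WT replicates 1, 2 and 3 held 21790983, 16728880 and 17356496 counted reads, and KO replicates 1, 2 and 3 held 17359620, 21429460 and 16420054. The genes with the highest mean counts were mt-Co1, the anion exchanger Slc4a1, Yam1, the carbonic anhydrase Car2, the glutathione peroxidase Gpx1 and the chaperone Hsp90ab1.

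Nfe2l2 transcripts were present in every library, at 81.6 ± 14.9 CPM in WT and 69.6 ± 6.75 CPM in KO (mean ± SD, n = 3 each). The log2 change was -0.23 (SE 0.140), with an adjusted p of 0.556 by edgeR and an exact two-sided permutation p of 0.3; without WT replicate 1 the change was -0.07. The gene lies on chromosome 2 from 75675513 to 75704641 (mm10). The deleted part is not given in the labels, and reads outside it check nothing about the genotype.

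Sex-linked transcripts divided the libraries. Xist, expressed from the inactive X of females, had 784, 884 and 1169 CPM on library totals in WT replicates 1, 2 and 3 and 917 in KO replicate 3, against 15.8 and 0.702 in KO replicates 1 and 2. Genes on chromosome Y summed to 212 and 272 CPM in KO replicates 1 and 2, 6.91 in KO replicate 3 and 0.289 to 1.20 in WT. KO replicate 3 was therefore also set alone against WT, with the spread taken from WT and from KO replicates 1 and 2. KO replicate 3 adds nothing to that spread and was treated as if it varied like the others. The comparison was chosen after seeing the data. It called 6 genes (4 higher and 2 lower) and 20 lists.

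**Figure D1:**
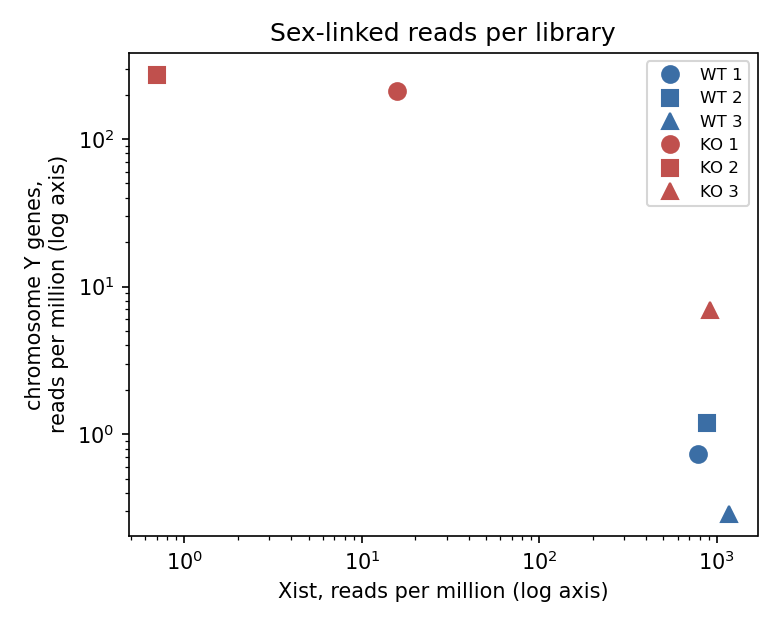
CPM on library totals of Xist (x axis) against CPM summed over chromosome Y genes (y axis), both on log axes, with 1 point per library. KO replicates 1 and 2 lie at 212 and 272 CPM of chromosome Y genes, and the WT libraries and KO replicate 3 at 784 to 1169 CPM of Xist.

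In KO cells 3 genes fell past the threshold over all 13721 genes tested, and 0 rose. Nqo1, the quinone oxidoreductase that is a classical Nrf2 target, went from 62.0 ± 17.0 to 14.6 ± 3.40 CPM (log2 -2.09, SE 0.223, adjusted p = 0.0301 by edgeR). It lies on chromosome 8 from 107388225 to 107403206. The complement component C3, on chromosome 17 from 57203970 to 57228136, went from 59.7 ± 4.06 to 24.7 ± 5.08 CPM (log2 -1.27, SE 0.153, adjusted p = 0.0301 by edgeR). Fn3k, a kinase that acts on sugar adducts of proteins, on chromosome 11 from 121434913 to 121450491, went from 235 ± 25.5 to 126 ± 11.7 CPM (log2 -0.90, SE 0.117, adjusted p = 0.0414 by edgeR). At an unadjusted p under 0.05 there were 1678 genes, 858 higher and 820 lower, where chance gives 686 on average. Splits of the libraries into 3 and 3 that mix WT and KO gave 292 to 1138. DESeq2 called 349 genes (83 higher and 266 lower) and limma-voom 4, and scaling by library totals called 33, 24 higher and 9 lower. With DESeq2 size factors 9 of 10 were lower.

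Single libraries moved these calls. The count was 0 without WT replicate 2 (by edgeR, with 1317 at an unadjusted p under 0.05), 1 without KO replicate 2, and 12 without either KO replicate 1 or KO replicate 3; without WT replicate 1 it was 4 and without WT replicate 3 it was 2. By edgeR, the adjusted p of Nqo1 was 0.146 without WT replicate 2 and 0.0903 without KO replicate 2. For C3 it was 0.0746, 0.146 and 0.0883 without WT replicates 1, 2 and 3. For Fn3k it was 0.173 and 0.108 without WT replicates 2 and 3 and 0.0513 and 0.0758 without KO replicates 1 and 2. For KO replicate 3 alone the log2 changes were -1.77 for Nqo1, -1.55 for C3 and -0.75 for Fn3k, with none of them past the threshold. Without single libraries the log2 changes were -2.28 to -1.84 for Nqo1, -1.46 to -1.16 for C3 and -0.99 to -0.84 for Fn3k.

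**Figure D2:**
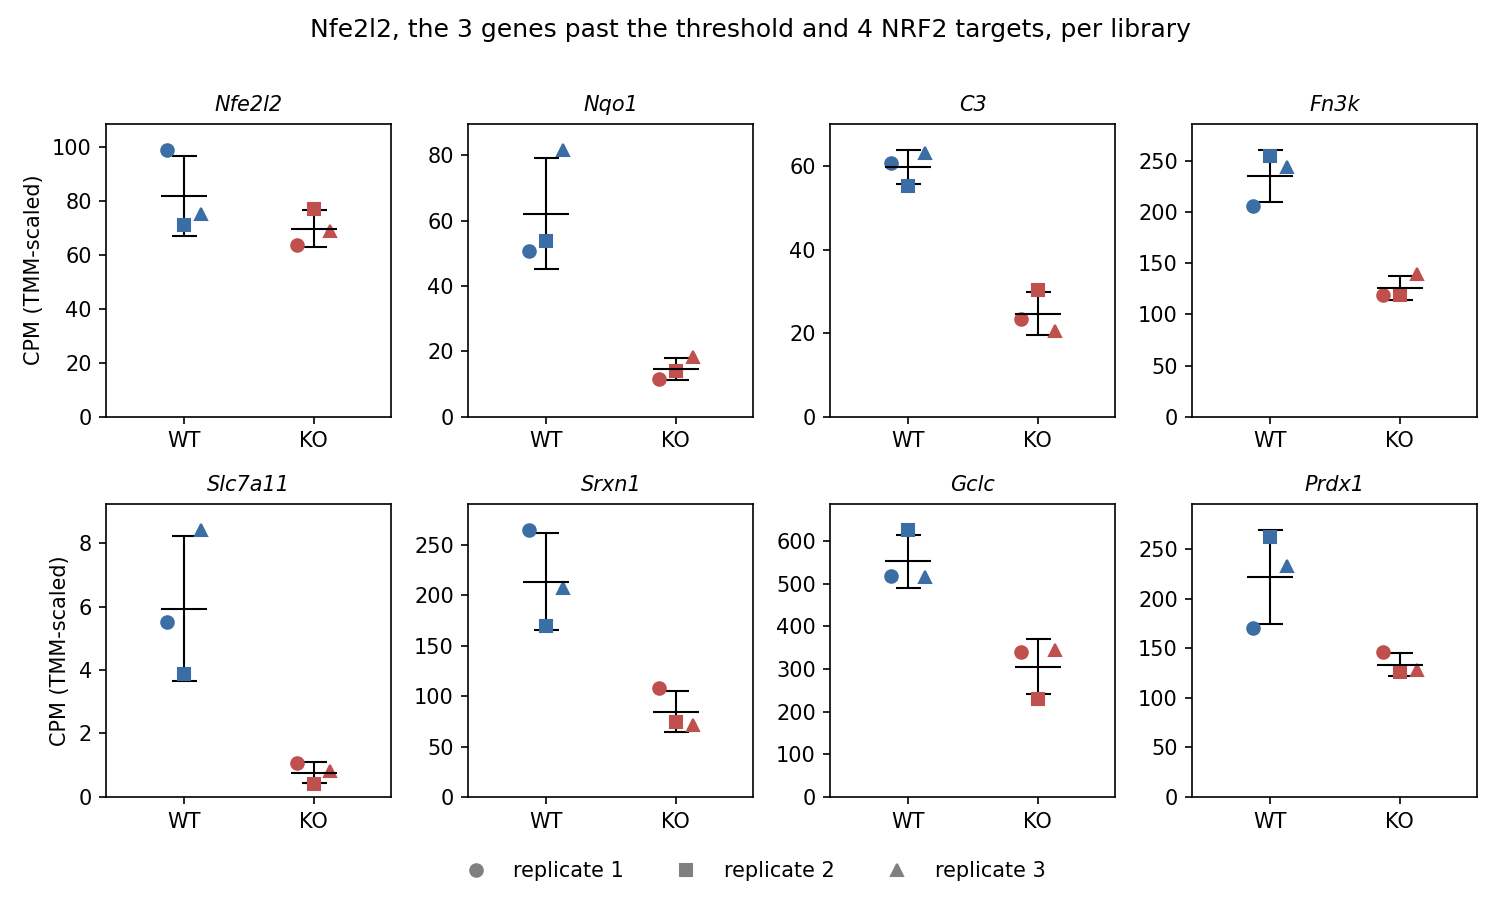
CPM (TMM-scaled, linear axes from 0) of Nfe2l2, Nqo1, C3, Fn3k, Slc7a11, Srxn1, Gclc and Prdx1 in each of the 6 libraries, with bars for the group mean and SD. Nqo1 lay at 11.5 to 18.2 CPM in KO and 50.7 to 81.5 CPM in WT.

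Nrf2 target genes formed the list with the lowest camera p. Of 40 tested, 34 were lower in KO, with a median log2 change of -0.65. Adjusted over the list alone 21 fell and 0 rose, and 1 fell over all genes (camera adjusted p = 4.46e-22, adjusted p = 0.170 with an estimated correlation). Scaling by library totals passed 3 higher and 14 lower over the list alone. Besides Nqo1, those fallen with TMM scaling included the cystine transporter Slc7a11 (5.93 ± 2.29 to 0.758 ± 0.334 CPM, log2 -2.97, SE 0.455), sulfiredoxin Srxn1 (log2 -1.34, SE 0.203), the glutamate-cysteine ligase subunit Gclc (log2 -0.86, SE 0.159) and peroxiredoxin Prdx1 (log2 -0.73, SE 0.150). The count of 21 became 8 without WT replicate 2. It was 3 for KO replicate 3 alone, the KO library with Xist. The median was -0.51 to -0.77 without single libraries and -0.38 for KO replicate 3 alone, with 32 of 40 lower in the last.

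Glutathione and thioredoxin genes were lower as groups. Of 32 glutathione genes 11 fell and 0 rose adjusted over the list alone, with 0 over all genes (median log2 -0.47; camera adjusted p = 1.69e-11, adjusted p = 0.235 with an estimated correlation). Among them were Slc7a11, Gclc, the glyoxalase Hagh (log2 -0.63) and the peroxidase Gpx1, which went from 8088 ± 1534 to 4523 ± 1053 CPM. By library totals the glutathione list had 1 higher and 9 lower. In the thioredoxin, peroxiredoxin and superoxide dismutase list of 23, 11 fell and 1 rose adjusted over the list alone, with 0 over all genes (median log2 -0.39; camera adjusted p = 3.42e-08, adjusted p = 0.360 with an estimated correlation). Srxn1, Prdx1 and the superoxide dismutase Sod1 (log2 -0.67) were among those that fell, and the glutaredoxin Glrx3 rose (log2 0.65, SE 0.124). KO replicate 3 alone had 3 glutathione genes fallen, and in the thioredoxin list 2 fell and 2 rose. Sod1 had a log2 of -0.42 there. The glutathione median was -0.35 to -0.55 without single libraries and -0.39 for KO replicate 3 alone, and the thioredoxin median was -0.22 without KO replicate 2, -0.26 to -0.56 without other single libraries and -0.24 for KO replicate 3 alone.

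Heme synthesis genes were lower as a group. Of 25 tested, 12 fell and 0 rose adjusted over the list alone, with 0 over all genes (median log2 -0.35; camera adjusted p = 1.96e-11, adjusted p = 0.170 with an estimated correlation), and 1 higher and 9 lower passed over the list alone by library totals. The glycine transporter Slc6a9 went from 195 ± 6.90 to 109 ± 15.9 CPM (log2 -0.84, SE 0.120) and the oxidase Ppox from 964 ± 105 to 532 ± 66.8 CPM (log2 -0.86). The X-linked Alas2, the erythroid enzyme of the first step, went from 6256 ± 299.6 to 3592 ± 738 CPM (log2 -0.80, SE 0.147). It stood at 3507, 2899.6 and 4368 CPM in KO replicates 1, 2 and 3. The transporter Abcb10 changed by a log2 of -0.61. KO replicate 3 alone had 2 fallen, and Alas2 at a log2 of -0.52. The heme synthesis median was -0.27 to -0.39 without single libraries and -0.37 for KO replicate 3 alone, where 20 of 25 were lower, against 20 with all libraries. In heme export and degradation 4 of 13 genes fell adjusted over the list alone and 0 over all genes (median log2 -0.24; camera adjusted p = 0.00946, adjusted p = 0.253 with an estimated correlation), while library totals gave 1 higher and 2 lower. Those fallen with TMM scaling were Abcg2 (log2 -0.68), the biliverdin reductase Blvrb (log2 -0.63) and the heme oxygenases Hmox2 (log2 -0.80) and Hmox1 (log2 -0.68). The median of this list was -0.15 without KO replicate 1, -0.19 to -0.27 without other single libraries and -0.30 for KO replicate 3 alone. Without WT replicate 2 these 4 became 0, with a camera adjusted p of 0.0546. They also became 0 for KO replicate 3 alone, at a camera adjusted p of 0.254, with Hmox2 at a log2 of -0.33 and Hmox1 at -0.44.

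Erythrocyte membrane and terminal differentiation genes were lower in 34 of 36 cases. Adjusted over the list alone 24 fell and 1 rose, with 0 over all genes (median log2 -0.34; camera adjusted p = 1.55e-18, adjusted p = 0.170 with an estimated correlation), and fry called this list (adjusted p = 0.0151). Protein 4.1 (Epb4.1) went from 5519 ± 514 to 3011 ± 267 CPM (log2 -0.87, SE 0.120) and Trim10 from 2395 ± 94.6 to 1362 ± 247 CPM, and protein 4.2 (Epb4.2) changed by a log2 of -0.71. The anion exchanger Slc4a1 went from 15794 ± 299.7 to 12102 ± 640.0 CPM (log2 -0.38). Pklr, the red cell pyruvate kinase, rose from 116 ± 12.2 to 170.0 ± 10.1 CPM (log2 0.55, SE 0.110). Leaving out KO replicate 3 reduced the 24 to 6, and library totals passed 1 higher and 3 lower. KO replicate 3 alone passed 0 members. The median was -0.32 to -0.38 without single libraries and -0.41 for KO replicate 3 alone.

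**Figure D3:**
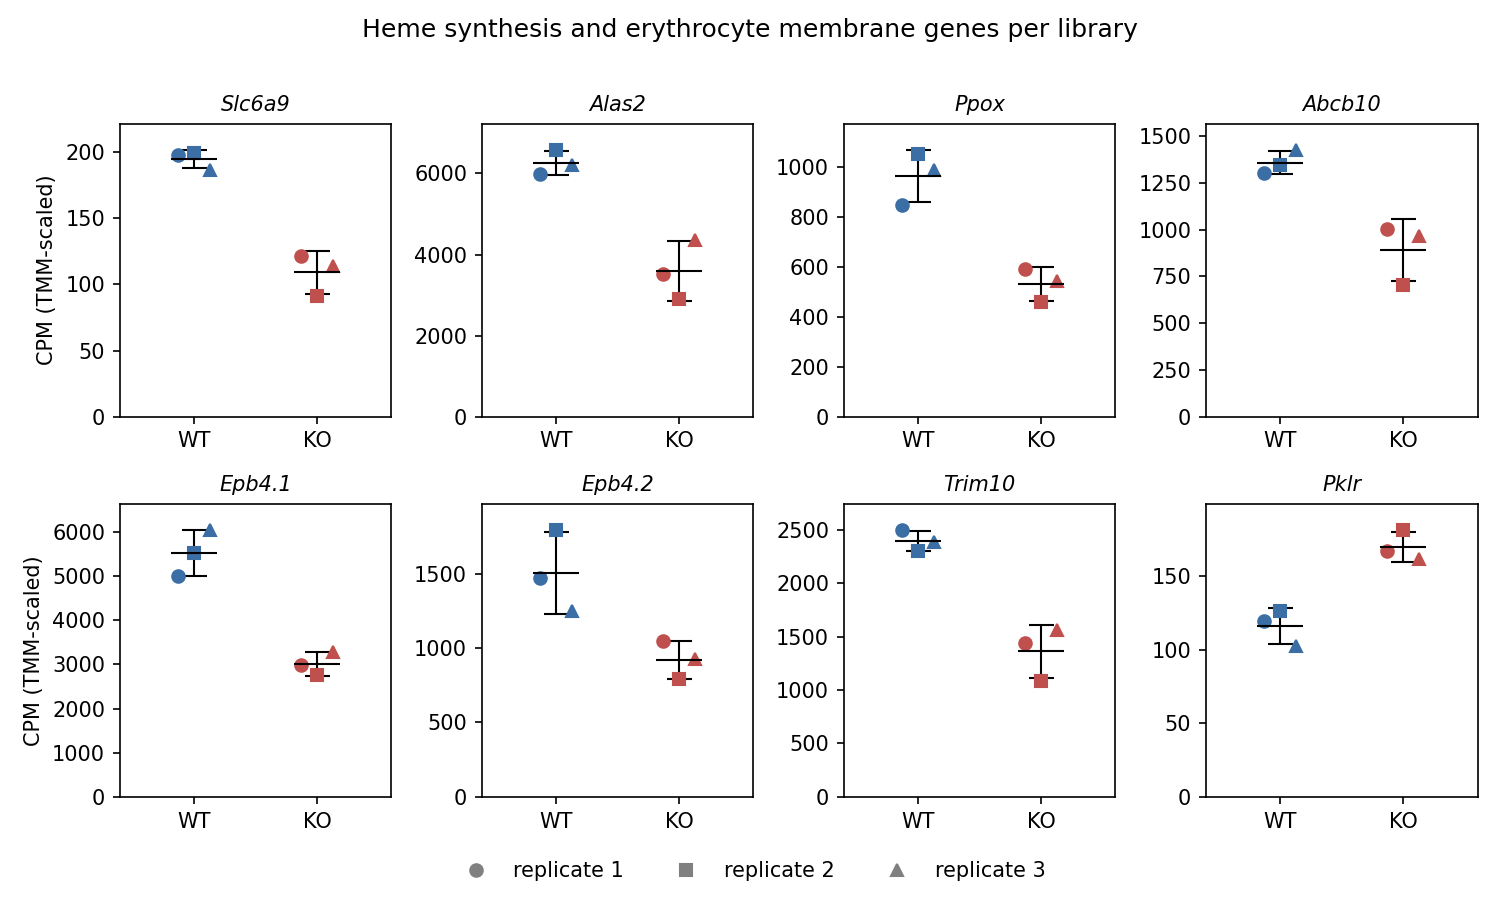
CPM (TMM-scaled, linear axes from 0) of the heme synthesis genes Slc6a9, Alas2, Ppox and Abcb10 and the erythrocyte genes Epb4.1, Epb4.2, Trim10 and Pklr in each library, with bars for the group mean and SD. Pklr was 116 ± 12.2 CPM in WT and 170.0 ± 10.1 CPM in KO, and the other genes were lower in KO, Alas2 at 2899.6 to 4368 CPM against 5980.5 to 6575 CPM in WT.

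Among erythroid transcription factors and regulators 7 of 29 fell and 0 rose adjusted over the list alone, with 0 over all genes (median log2 -0.10; camera adjusted p = 0.000166, adjusted p = 0.170 with an estimated correlation). Trim58 (log2 -0.81, SE 0.129), Klf3 (log2 -0.74), Tal1 (log2 -0.67) and E2f2 (log2 -0.75) led them. Scaling by library totals moved the median of all genes from 0.02 to 0.15 and that of this list to 0.03. Scaling shifts all genes by about the same amount, so the -0.12 relative to all genes is no check of it. The median was -0.20 without KO replicate 2, -0.09 to -0.14 without other single libraries and -0.25 for KO replicate 3 alone. The number fallen was 3 without WT replicate 2 and 0 for KO replicate 3 alone, where 20 of 29 were lower, as against 20 with all libraries, and E2f2 had a log2 of -0.43. Autophagy and organelle clearance genes had 7 of 29 lower adjusted over the list alone and 0 over all genes (median log2 -0.23; camera adjusted p = 1.67e-05, adjusted p = 0.170 with an estimated correlation). They included the mitophagy genes Pink1 (log2 -0.73) and Bnip3l (log2 -0.54), with Gabarapl2 (log2 -0.52) and the X-linked lysosomal gene Lamp2 (log2 -0.61). Their number was 1 without WT replicate 2, KO replicate 2 or KO replicate 3, and 0 without WT replicate 3 or for KO replicate 3 alone. The autophagy median was -0.19 to -0.25 without single libraries and -0.33 for KO replicate 3 alone.

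Iron handling genes were lower by a median log2 of -0.31, with 5 of 22 fallen adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00162, adjusted p = 0.253 with an estimated correlation). They were the iron chaperone Pcbp1 (log2 -0.72), the transferrin receptor Tfrc (2958 ± 250.0 to 1776 ± 307 CPM, log2 -0.74), the ferritinophagy receptor Ncoa4 (log2 -0.70), Aco1 (log2 -0.81) and ferritin heavy chain Fth1 (3272 ± 653 to 1898 ± 613 CPM, log2 -0.79). The median was -0.06 without WT replicate 1, -0.57 without KO replicate 1, -0.20 without KO replicate 2, -0.25 to -0.44 without other single libraries and -0.28 for KO replicate 3 alone. By library totals 4 higher and 4 lower passed over the list alone. The list had 8 fallen and 1 risen without WT replicate 1, 7 fallen and 1 risen without KO replicate 1, and 3 fallen without WT replicate 2 or KO replicate 2. It had 0 fallen for KO replicate 3 alone, with a camera adjusted p of 0.0955, 15 of 22 lower against 13 with all libraries, Aco1 at a log2 of -0.46 and Fth1 at -0.33.

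Genes that protect from ferroptosis had 3 of 25 lower adjusted over the list alone and 0 over all genes: Slc7a11 (log2 -2.97), its partner Slc3a2 (log2 -0.63) and the cyclohydrolase Gch1 (log2 -0.63, SE 0.110). The median log2 was -0.10, or 0.03 by library totals, -0.13 relative to all genes (camera adjusted p = 0.00689, adjusted p = 0.360 with an estimated correlation); by library totals 1 higher and 2 lower passed over the list alone. The median was -0.07 without WT replicate 2, -0.07 to -0.15 without other single libraries and -0.11 for KO replicate 3 alone. The number fallen was 6 without KO replicate 1, 5 without KO replicate 3 and 0 for KO replicate 3 alone, and 2 fell and 2 rose without WT replicate 2. The camera adjusted p was 0.0728 without WT replicate 2, 0.0595 without KO replicate 2 and 0.181 for KO replicate 3 alone. Genes that promote ferroptosis had 6 lower and 3 higher of 31 adjusted over the list alone and 0 over all genes (median log2 -0.27; camera adjusted p = 0.00736, adjusted p = 0.360 with an estimated correlation). Tfrc, Ncoa4, Aco1 and Hmox1 fell, and Pebp1 (log2 0.42) and the desaturase Fads2 (log2 0.48) rose. The balance turned by library totals, with 4 higher and 2 lower over the list alone, and upper-quartile scaling gave 1 higher and 6 lower. The median relative to all genes was -0.29 by library totals and by TMM, since scaling shifts all genes by about the same amount. The median of this list was -0.16 without WT replicate 2, -0.12 without WT replicate 3, -0.14 without KO replicate 3, -0.19 to -0.28 without other single libraries and -0.29 for KO replicate 3 alone. The counts lower and higher were 3 and 0 without KO replicate 1, 3 and 2 without KO replicate 2 (camera adjusted p = 0.0506), 5 and 0 without KO replicate 3 and 2 and 0 without WT replicate 3. Both were 0 without WT replicate 2 and for KO replicate 3 alone.

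Genes of 2-hydroxyglutarate and 2-oxoglutarate metabolism were higher on balance. Adjusted over the list alone 5 of 27 rose and 1 fell, with 0 over all genes (median log2 0.18; camera adjusted p = 0.000514, adjusted p = 0.253 with an estimated correlation). The serine synthesis enzymes Phgdh (21.2 ± 3.22 to 44.4 ± 5.92 CPM, log2 1.07, SE 0.156) and Psat1 (log2 0.72, SE 0.129) rose, with lactate dehydrogenase Ldha (185 ± 6.04 to 275 ± 26.5 CPM, log2 0.57) and Idh3a (log2 0.49). Without KO replicate 1 or WT replicate 2, and for KO replicate 3 alone, 3 rose. By edgeR 0 fell without KO replicate 1, KO replicate 2, WT replicate 2 or WT replicate 3 or for KO replicate 3 alone. The median was 0.11 without WT replicate 1, 0.11 without KO replicate 1, 0.15 to 0.19 without other single libraries and 0.18 for KO replicate 3 alone. In the citric acid cycle list of 21, Idh3a and the X-linked Pdha1 (log2 0.38) rose and the carboxylase Pcx (log2 -0.54) fell adjusted over the list alone, with 0 over all genes (median log2 0.18; camera adjusted p = 0.00223, adjusted p = 0.253 with an estimated correlation). No member passed without KO replicate 1, KO replicate 3 or WT replicate 2 or for KO replicate 3 alone; 1 fell and 0 rose without WT replicate 1, and 1 rose without WT replicate 3 or with X and Y genes left out. Library totals passed 15 higher and 1 lower in this list and upper-quartile scaling 1 higher and 1 lower. The citric acid cycle median was 0.11 without KO replicate 1, 0.15 to 0.20 without other single libraries and 0.18 for KO replicate 3 alone.

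Mitotic genes were lower in 38 of 38 cases by a median log2 of -0.21. Pttg1 (log2 -0.47) and Ube2c (log2 -0.38) fell adjusted over the list alone, with 0 over all genes (camera adjusted p = 4.91e-09, adjusted p = 0.366 with an estimated correlation). The median was -0.31 without KO replicate 2, -0.17 to -0.24 without other single libraries and -0.27 for KO replicate 3 alone. The 2 became 21 without KO replicate 2 and 0 without KO replicate 1, KO replicate 3 or any WT replicate and for KO replicate 3 alone. Cytosolic ribosomal protein genes were higher in 80 of 83 cases, with a median log2 of 0.20 and 0 past the threshold adjusted over the list alone or over all genes (camera adjusted p = 1.52e-07, adjusted p = 0.683 with an estimated correlation). By edgeR 13 of them had an unadjusted p under 0.05, and DESeq2 and limma-voom passed 0. The ribosomal protein median was 0.11 without KO replicate 1, 0.15 to 0.28 without other single libraries and 0.24 for KO replicate 3 alone. Rps2 stood at 1537 ± 42.9 CPM in WT and 1908 ± 59.0 CPM in KO. Interferon response genes were lower in 36 of 44 cases, with 0 past the threshold adjusted over the list alone or over all genes (median log2 -0.22; camera adjusted p = 0.000483, adjusted p = 0.460 with an estimated correlation). Rsad2 stood at 4375 ± 738 CPM in WT and 2902 ± 297 CPM in KO. By edgeR 4 interferon genes had an unadjusted p under 0.05, and over the list alone DESeq2 passed 2 and limma-voom 1 as lower. Leaving out KO replicate 1 gave 4 fallen and 1 risen, WT replicate 2 gave 4 fallen and KO replicate 2 gave 2. The interferon median was -0.15 without WT replicate 3, -0.19 to -0.30 without other single libraries and -0.02 for KO replicate 3 alone, where 24 of 44 were lower and the camera adjusted p was 0.389.

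Replication-dependent histone genes had a median log2 of -0.32 (camera adjusted p = 0.00236, adjusted p = 0.583 with an estimated correlation), and Hist2h2be stood at 32.0 ± 3.58 CPM in WT and 19.7 ± 3.09 CPM in KO. The call was lost without WT replicate 2 (0.173) and without KO replicate 1 (0.231). For KO replicate 3 alone 28 of 53 were higher, against 14 with all libraries, and the median was -0.01 relative to all genes. Nuclear-encoded respiratory chain genes had a median of 0.14 (camera adjusted p = 0.00809, adjusted p = 0.764 with an estimated correlation), a call lost without WT replicate 1 (0.210), WT replicate 2 (0.204), KO replicate 1 (0.681) or KO replicate 3 (0.0544). Proteasome genes had a median of 0.10 (camera adjusted p = 0.0178, adjusted p = 0.741 with an estimated correlation), lost without WT replicate 1 (0.0784), WT replicate 2 (0.0908) or KO replicate 1 (0.445) and for KO replicate 3 alone (0.254). Nrf2 regulators had a median of -0.28 (camera adjusted p = 0.0274, adjusted p = 0.460 with an estimated correlation), lost without WT replicate 1 (0.189), WT replicate 3 (0.0518), KO replicate 2 (0.0506) or KO replicate 3 (0.195). The 5 tested globins had a median of -0.42 (camera adjusted p = 0.0274, adjusted p = 0.460 with an estimated correlation), lost without WT replicate 3 (0.514), KO replicate 1 (0.0641) or KO replicate 2 (0.153) and for KO replicate 3 alone (0.323). The histone median was -0.08 without WT replicate 2, -0.22 to -0.44 without other single libraries and 0.02 for KO replicate 3 alone. That of the respiratory chain was 0.06 without WT replicate 2, 0.22 without WT replicate 3, 0.03 without KO replicate 1, 0.08 without KO replicate 3, 0.11 to 0.20 without other single libraries and 0.17 for KO replicate 3 alone. The proteasome median was 0.00470 without KO replicate 1, 0.09 to 0.13 without other single libraries and 0.07 for KO replicate 3 alone. For Nrf2 regulators it was -0.15 without WT replicate 1, -0.20 to -0.39 without other single libraries and -0.34 for KO replicate 3 alone. The globin median was -0.21 without WT replicate 3, -0.69 without KO replicate 3, -0.37 to -0.62 without other single libraries and -0.14 for KO replicate 3 alone. Of the 5, Hba-x, Hbb-y and Hbb-bh1 are embryonic, and Hbb-y had only 11 to 30 and Hbb-bh1 14 to 42 reads per library. Adult globin genes have near-identical copies between which reads may be split, so the values of adult members alone carry this doubt. In each of these lists 0 members passed adjusted over the list alone or over all genes by edgeR, with 6 histone, 12 respiratory chain, 7 proteasome, 3 Nrf2 regulator and 0 globin genes at an unadjusted p under 0.05. Scaling by library totals passed 11 respiratory chain and 8 proteasome genes as higher over the list alone. Over the list alone DESeq2 passed 1, 1, 1, 1 and 0 as lower and limma-voom 0, 0, 0, 1 and 0. Leaving out KO replicate 2 gave 1 histone gene fallen and 1 proteasome gene risen and 1 fallen, and leaving out KO replicate 3 gave 1 globin fallen. Leaving out WT replicate 1 gave 1 respiratory chain gene fallen, and 1 Nrf2 regulator fell without WT replicate 2 and for KO replicate 3 alone.

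**Figure D4:**
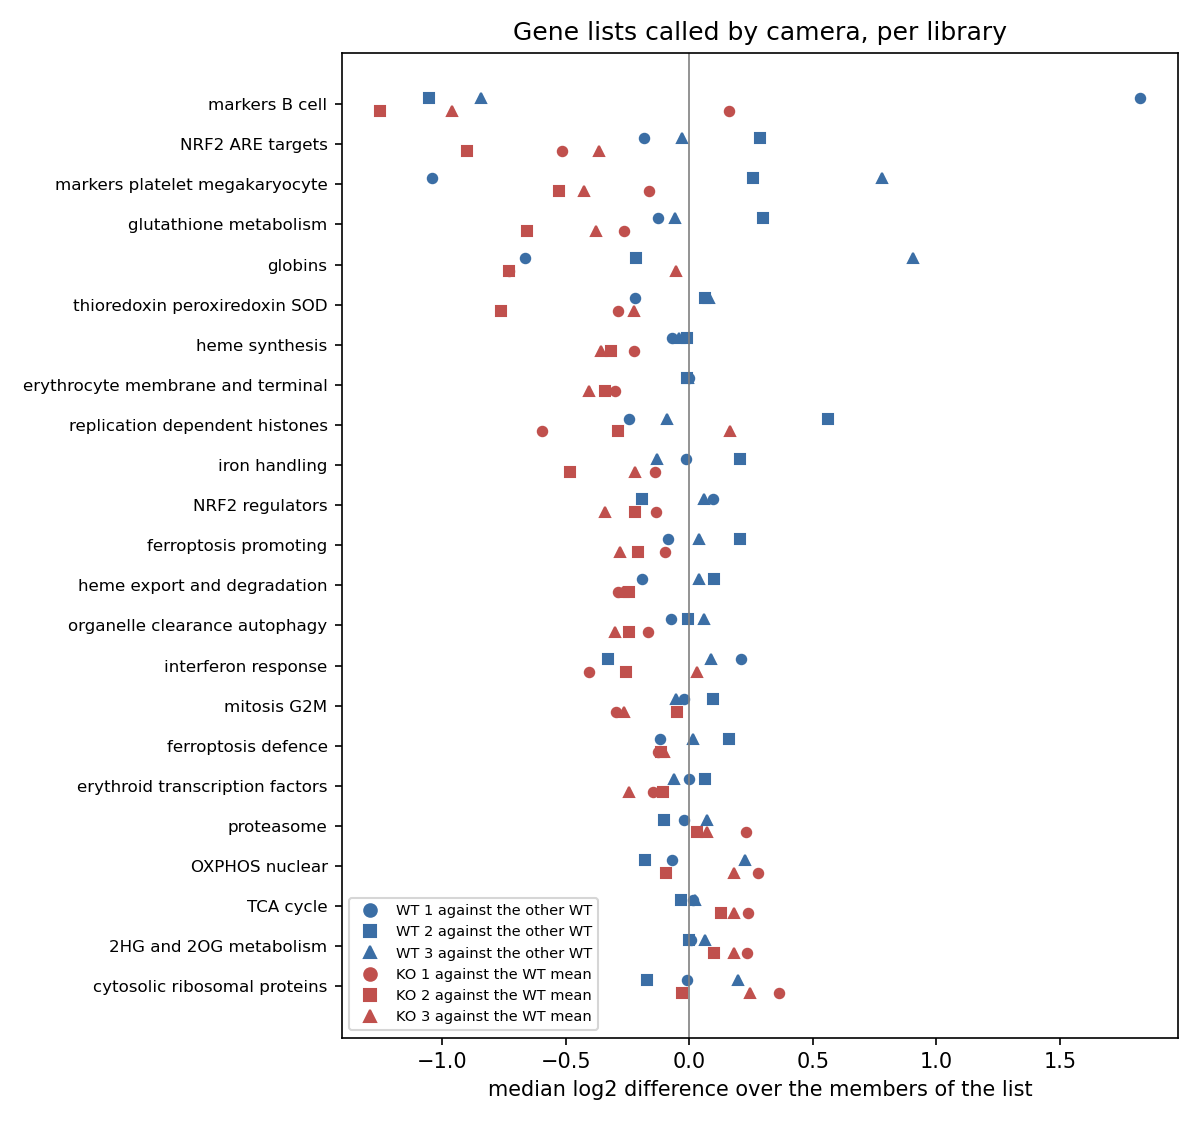
Median log2 difference over the members of each of the 23 gene lists called by camera, for each KO library against the WT mean and for each WT library against the other WT libraries. Medians of the Nrf2 target list were -0.51, -0.90 and -0.36 in KO replicates 1, 2 and 3 and -0.18 to 0.29 in single WT libraries.

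Lists that camera did not call also held members that moved. In glycolysis 7 rose and 4 fell of 26 adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.587). Ldha, Pklr and Tpi1 (log2 0.43) rose, and the phosphofructokinase Pfkp (20.7 ± 7.55 to 7.13 ± 1.97 CPM, log2 -1.54, SE 0.289) fell; 2 fell without WT replicate 3. In the integrated stress response list of 33, 4 rose, Phgdh and Psat1 among them, and 4 fell adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.670). Slc7a11, Slc3a2 and the stress factor Ddit3 (log2 -1.04, SE 0.201) were lower, and 2 fell without WT replicate 2. Among 27 HIF targets 3 rose adjusted over the list alone, Pdk1 (log2 0.58, SE 0.103), Ldha and the X-linked Pgk1 (log2 0.39). In the same way 5 fell, Tfrc, Bnip3l and Hmox1 among them, with 0 past the threshold over all genes (camera adjusted p = 0.620). By library totals the balance of HIF targets turned, with 4 higher and 2 lower, and 6 higher and 3 lower passed in the integrated stress response list. HIF targets fallen numbered 3 without KO replicate 3 and 1 without WT replicate 2 or WT replicate 3. With KO replicate 3 alone 0 glycolysis and 0 HIF genes passed by edgeR, and in the integrated stress response list 2 rose and 2 fell. The log2 changes in that library were 0.59 for Ldha, 0.48 for Tpi1, -1.13 for Pfkp, 0.52 for Pdk1 and 0.37 for Pgk1.

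In the pentose phosphate and NADPH list of 17, Mthfd1 (log2 0.51) and Nadk (log2 0.49) rose and Taldo1 (log2 -0.61) and Me1 (log2 -1.09) fell adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.559); 4 rose and 3 fell without KO replicate 2, 1 fell without WT replicate 2 or WT replicate 3, and 0 did for KO replicate 3 alone, where Taldo1 had a log2 of -0.33 and Me1 of -1.31. By library totals 6 higher and 2 lower passed. The p53 targets Trp53inp1 (log2 -0.54) and Btg2 (log2 -0.79) fell of 25 adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.162), and 1 fell for KO replicate 3 alone, with log2 changes of -0.74 and -0.68. The mitochondrial chaperone Hspd1 (log2 0.59, SE 0.108) and Hspa4 (log2 0.40) rose in the heat shock list of 19 adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.792); 1 did without KO replicate 1, KO replicate 2 or WT replicate 3, and 1 fell without WT replicate 2. With DESeq2 size factors or upper-quartile scaling 2 heat shock genes were higher and 1 lower. Camera called the heat shock list higher without WT replicate 1 (adjusted p = 0.0167, median log2 0.16) and lower without WT replicate 2 (adjusted p = 0.0196, median log2 -0.32). In the progenitor list of 20, Tfrc and the erythropoietin receptor Epor (log2 -0.72) fell and Rexo2 (log2 0.39) rose adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.670). Rexo2 was the 1 member higher; 0 were without KO replicate 1, KO replicate 3 or any WT replicate. Library totals passed 2 higher and 2 lower in this list, and DESeq2 size factors or upper-quartile scaling 0 higher and 2 lower. The list of 2-oxoglutarate-dependent dioxygenases (32 genes, camera adjusted p = 0.587) held enzymes that act on DNA and histones, and others such as Egln1 and Fto. In it the X-linked demethylases Kdm6a (log2 -0.79) and Kdm5c (log2 -0.43) fell adjusted over the list alone, with 0 over all genes. Kdm6a stood at 219 to 250.1 CPM in WT and at 114, 118 and 170.0 CPM in KO replicates 1, 2 and 3. With X and Y genes left out, without WT replicate 2 or for KO replicate 3 alone, 0 members fell, and 1 without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 3. By library totals 1 higher and 1 lower passed. In KO replicate 3 alone Kdm6a had a log2 of -0.44 and Kdm5c of -0.36.

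The other pathway lists that camera did not call had 0 members past the threshold adjusted over the list alone or over all genes by edgeR. At an unadjusted p under 0.05 there were 3 cholesterol synthesis, 3 NF-kB, 0 mitochondrial genome, 8 apoptosis, 12 fatty acid, 0 DNA replication and 5 methyltransferase genes. Over the list alone DESeq2 passed 2 fatty acid genes as higher and 7 as lower, and DESeq2 and limma-voom passed no other member of these lists. Their median log2 changes were 0.16 for cholesterol synthesis (camera adjusted p = 0.0512), 0.17 for NF-kB inflammation (0.162), -0.30 for respiratory chain genes of the mitochondrial genome (0.162) and 0.06 for apoptosis regulators (0.667). Relative to all genes, the medians were -0.01 for fatty acid genes (0.559), -0.02 for DNA replication (0.657) and -0.05 for DNA and histone methyltransferases (0.964). Without WT replicate 1, 2 fatty acid genes rose and 6 fell, 4 rose without WT replicate 2, and 1 methyltransferase gene rose without KO replicate 2. Camera called cholesterol synthesis higher without WT replicate 2 (adjusted p = 0.00169) or KO replicate 3 (0.0133), and mitochondrial genome genes lower without WT replicate 1 (5.19e-05) or for KO replicate 3 alone (0.000284). DNA replication genes were called lower for KO replicate 3 alone (0.0372). The cholesterol synthesis median was 0.09 without WT replicate 3, 0.07 without KO replicate 1, 0.11 to 0.21 without other single libraries and 0.10 for KO replicate 3 alone. The NF-kB median was 0.31 without WT replicate 1, 0.05 without WT replicate 3, 0.05 without KO replicate 1, 0.12 to 0.20 without other single libraries and 0.07 for KO replicate 3 alone. For mitochondrial genome genes it was -0.54 without WT replicate 1, 0.20 without WT replicate 3, -0.06 without KO replicate 3, -0.34 to -0.42 without other single libraries and -0.71 for KO replicate 3 alone, and without WT replicate 3, where the direction turned, 11 of 12 were higher. For apoptosis regulators it was 0.03 without WT replicate 2, -0.00654 without WT replicate 3, -0.03 without KO replicate 1, 0.02 without KO replicate 2, 0.04 without KO replicate 3, 0.05 without WT replicate 1 and -0.08 for KO replicate 3 alone. Relative to all genes it turned for fatty acid genes, at 0.00639 without KO replicate 3, and for DNA replication, at 0.03 without KO replicate 3. Median, mean and test differed in sign for the fatty acid, pentose phosphate, glycolysis, HIF, DNA replication, integrated stress response, progenitor, heat shock, mast cell and methyltransferase lists, none of which was called.

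Markers of other cells were measured for contents of the sorted fraction. Platelet and megakaryocyte markers had a median log2 of -0.49, with Gp9 (31.7 ± 4.07 to 20.7 ± 0.634 CPM, log2 -0.62) fallen adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000483, adjusted p = 0.583 with an estimated correlation). The camera call was lost without WT replicate 3 (0.187), and the median was -0.13 without WT replicate 3, -0.36 to -0.68 without other single libraries and -0.57 for KO replicate 3 alone. The number fallen was 14 without WT replicate 1 and 0 without KO replicate 1, KO replicate 3 or WT replicate 2 and for KO replicate 3 alone. B cell markers were lower in 15 of 15 cases by a median log2 of -0.74, with 0 past the threshold adjusted over the list alone or over all genes by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0127, adjusted p = 0.741 with an estimated correlation). With the replicate number as a block, which was not shown to pair these libraries, 5 of them passed as lower over the list alone. Their sum was highest in WT replicate 1, at 1557 CPM on library totals. The median was 0.20 without WT replicate 1, -1.14 without WT replicate 2, -1.59 without KO replicate 1, -0.50 to -1.02 without other single libraries and -1.17 for KO replicate 3 alone. Without WT replicate 1 the camera adjusted p was 0.954; it was 0.194 without KO replicate 2 and 0.212 without KO replicate 3. Macrophage and monocyte markers summed, on library totals, to 2894 ± 67.0 CPM in WT and 3538 ± 473 CPM in KO (exact permutation p = 0.1, two-sided, the smallest possible). TMM factors were 0.9375 to 0.9716 in WT and 1.029 to 1.068 in KO, so TMM-scaled sums would lie closer together. With TMM the median log2 of these markers was 0.19 (camera adjusted p = 0.114). Camera called them higher without KO replicate 2 (adjusted p = 0.0218) and for KO replicate 3 alone (0.0214). The macrophage median was 0.09 without KO replicate 1, 0.09 without KO replicate 3, 0.17 to 0.19 without other single libraries and 0.27 for KO replicate 3 alone. The most abundant members were Slc40a1, also in the iron list (515 ± 144 CPM in WT and 318 ± 72.4 in KO), Vcam1 (474 ± 67.8 and 541 ± 82.4) and Lyz2 (275 ± 35.0 and 368 ± 125).

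The other marker lists were not called and, as for macrophages, had 0 members past the threshold adjusted over the list alone or over all genes by edgeR. At an unadjusted p under 0.05 there were 4 macrophage, 2 T cell and 1 endothelial or stromal markers and 0 in each of the others; over the list alone DESeq2 passed 1 macrophage and 1 endothelial or stromal marker as lower and limma-voom 0. Their median log2 changes were 0.25 for NK cells (camera adjusted p = 0.587), -0.15 for T cells (0.313), -0.24 for neutrophils (0.256), -0.33 for endothelium and stroma (0.0689) and -0.36 for plasma cells (0.201). Relative to all genes, the medians were -0.03 for dendritic cells (0.837) and 0.00871 for mast cells, basophils and eosinophils (0.935). Without WT replicate 1, 4 neutrophil markers and 1 macrophage marker fell. Without KO replicate 3, 3 endothelial or stromal markers fell, and 2 plasma cell markers without KO replicate 1. Camera called neutrophil markers lower without WT replicate 1 (adjusted p = 1.33e-06) or KO replicate 2 (0.0148), endothelial and stromal markers without WT replicate 3 (0.0105) or KO replicate 3 (6.29e-05), plasma cell markers without KO replicate 1 (3.89e-08) or for KO replicate 3 alone (0.0372), and T cell markers without KO replicate 1 (0.0198). The NK cell median was 0.07 without WT replicate 2, 0.08 without KO replicate 2, 0.13 without KO replicate 3, 0.20 to 0.27 without other single libraries and 0.25 for KO replicate 3 alone. The T cell median was 0.17 without WT replicate 1, -0.27 without WT replicate 2, -0.35 without WT replicate 3, -0.42 without KO replicate 1, -0.00770 without KO replicate 2, -0.05 without KO replicate 3 and -0.46 for KO replicate 3 alone, and 11 of 17 were higher without WT replicate 1. The neutrophil median was -0.47 without WT replicate 1, 0.09 without WT replicate 3, -0.15 without KO replicate 1, -0.42 without KO replicate 2, -0.10 without KO replicate 3, -0.17 without WT replicate 2 and -0.39 for KO replicate 3 alone, and 13 of 20 were higher without WT replicate 3. The endothelial and stromal median was -0.08 without WT replicate 1, -0.12 without WT replicate 2, -0.62 without WT replicate 3, -0.83 without KO replicate 3, -0.23 to -0.29 without other single libraries and 0.06 for KO replicate 3 alone, where 8 of 16 were higher against 5 with all libraries. The plasma cell median was -0.24 without WT replicate 1, -0.22 without WT replicate 3, -1.37 without KO replicate 1, 0.02 without KO replicate 2, -0.10 without KO replicate 3, -0.29 without WT replicate 2 and -0.88 for KO replicate 3 alone. Relative to all genes it turned for dendritic cells, at 0.12 without WT replicate 1, 0.07 without WT replicate 3 and 0.10 without KO replicate 3, and for mast cells, basophils and eosinophils, at -0.20 without WT replicate 1, -0.05 without KO replicate 1 and -0.17 without KO replicate 2.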

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

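KO replicate 3 alone, X and Y genes left out and the removal of GC and length trends were chosen after seeing the data. The count of 3 genes was 10 with DESeq2 size factors, 8 with upper-quartile scaling, 33 with library totals, 349 with the DESeq2 Wald test, 4 with limma-voom, 228 with no low-count filter, 9 with the stricter filter, 9 without the most abundant genes and globins, 13 without marker and antigen receptor genes and 9 without X and Y genes, and each of these calls included the 3. By edgeR it was 0 against a fold of 1.5, a stricter test by construction (122 at an unadjusted p under 0.05), and 6 for KO replicate 3 alone, sharing 0. Apart from that the cause was not tested. Leaving out single libraries gave 0 to 12 genes and 20 to 22 lists, against 23. With the replicate block 9 genes and 24 lists passed. The numbers were not shown to pair the libraries. Same-numbered deviations correlated by 0.110, 0.0647 and 0.00340. Those of replicates 1 and 2 were the highest of all pairs, but neither replicate 3 correlated best with its own number. An estimated correlation left 0 lists and fry 1. The B cell list ranged from -1.59 to 0.20 without single libraries and reversed without WT replicate 1. With library totals, the members lower adjusted over the list alone were 14 for Nrf2 targets, 9 for heme synthesis and 3 for the erythrocyte membrane, beside 3, 1 and 1 higher. In the same setting 28 ribosomal protein, 15 citric acid cycle and 13 genes of 2-oxoglutarate metabolism were higher. The list medians relative to all genes were -0.67, -0.37, -0.36, 0.18, 0.16 and 0.16 both with library totals and with TMM. A change of scaling shifts all genes by about the same amount, so these relative medians could hardly differ and are no check of scaling. Library totals also gave 0 autophagy, 0 mitotic, 2 erythroid factor and 4 iron genes lower over the list alone by edgeR, and 4 iron, 11 respiratory chain, 8 proteasome, 4 apoptosis, 4 methyltransferase, 3 cholesterol and 6 pentose phosphate genes higher. The block gave 5 B cell marker, 2 HIF, 2 integrated stress response, 1 pentose phosphate and 1 globin genes lower, and 3 HIF and 5 integrated stress response genes higher. Nfe2l2 stayed between -0.32 and -0.07 in every setting run. A count over settings took the named genes with an unadjusted p under 0.05 by edgeR, without those named only for a high mean count. Of its values 2153 kept their direction and side of the threshold, 168 came to pass and 15 ceased to. Only Nqo1, C3 and Fn3k passed in the main test and could cease to, so the 15 are all theirs and most of the 2153 never passed. For called lists 267 kept direction and side and 75 ceased to pass. Removing GC and length trends moved the Nrf2 target median from -0.65 to -0.66. At these depths edgeR recovered 64.5% of simulated changes of 1 log2 unit, so smaller ones can be missed.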

Other observations

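Over all genes 42 had an adjusted p under 0.1 by edgeR, 12 higher and 30 lower, and 4 of them outside the fixed lists are given here, chosen after their values were seen. Hif1a, a subunit of the hypoxia-inducible factor, stood at 31.0 ± 9.80 CPM in WT and 10.6 ± 1.09 CPM in KO (log2 -1.54, SE 0.219, adjusted p = 0.0528 by edgeR). The fatty acid transporter Cd36 stood at 356 ± 53.4 and 211 ± 9.32 CPM (log2 -0.76, adjusted p = 0.0736 by edgeR). The mitochondrial chaperone Hspa9 was higher, at 158 ± 3.18 CPM in WT and 245 ± 17.1 CPM in KO (log2 0.64, SE 0.0989, adjusted p = 0.0575 by edgeR), and so was the nucleolar protein Npm1 (log2 0.64, adjusted p = 0.0906 by edgeR). In each of these genes the KO values lay on one side of the WT values. That held for 2492 genes, or 18.2% of those tested, where chance gives 10%.

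Reads on adult mouse globin genes were few for erythroid cells, and how reads that match several of their copies were counted is not given in the sources used here. Hbb-bt had 4 to 10 reads per library, Hbb-bs 0 to 7, Hba-a1 0 to 9 and Hba-a2 350 to 974, while the embryonic Hba-x had 5855 to 12157. The sickle line is not given in the labels, and human globin transcripts were not analysed here. KO replicate 1 held 274 Xist reads beside 1510 of the Y-linked Ddx3y, and KO replicate 3 held 29 Ddx3y reads beside 15014 of Xist. The lines with date-like names, tested apart, gave 0 calls among 21 by edgeR (4 at an unadjusted p under 0.05).

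The tests on sex, on other cells and on maturity below were chosen after the results were seen, those on sex and other cells in place of earlier versions, and those on splits and on flanking DNA before. For the lower Nrf2 targets, unequal sex is a candidate explanation. In KO replicate 3, with Xist, the list median was -0.36, against -0.75 in the other KO libraries and -0.18 to 0.29 in single WT libraries. That lies below the WT range, but 1 library cannot settle whether sex is the whole source. Dilution by cells of another type, which a Ter119 sort is meant to remove, would raise the markers of that type. Of the 10 marker lists, that of macrophages stood highest relative to its SE, by 0.12 log2 units (SE 0.0652 over libraries). Its sums on library totals were 3024 to 3954 CPM in KO and 2828 to 2962 CPM in WT, a scaling that sets KO higher than TMM does. These values neither show nor exclude dilution. Loss of Nrf2 stays a hypothesis beside sex and dilution.

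The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3 genes and the highest other 8, with WT replicates 1 and 2 and KO replicate 2 against the rest. For lists the real split gave 23 and the others 5 to 17.

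The lower heme synthesis and erythrocyte membrane genes may have the same candidate sources. In KO replicate 3 the list medians were -0.36 and -0.41, against -0.27 and -0.31 in the other KO libraries and -0.07 to -0.01 and -0.01 to -0.000233 in single WT libraries. Both medians of KO replicate 3 lie below the WT ranges, but a single library leaves sex open, and the macrophage change of 0.12 leaves dilution open. A shift towards less mature cells would raise progenitor and mitotic genes. The progenitor list, not called, had a median of 0.0401, with members going both ways. This median was -0.01 without WT replicate 2, -0.04 without KO replicate 3 and -0.00297 with upper-quartile scaling. The list shares Car1 and Ermap with the erythrocyte membrane list and Mpo and Ctsg with the neutrophil markers, so it is a poor measure of maturity. Mitotic genes went against that prediction, lower in 38 of 38 cases. Their median was -0.297, -0.0487 and -0.264 in KO replicates 1, 2 and 3 and -0.0547 to 0.0950 in single WT libraries. KO replicate 2 lay within the WT range, so a shift in maturity was not shown and is not excluded. Sex, dilution and genotype stay open too.

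A knockout on a mixed background can carry DNA of another strain around the targeted gene, which might by itself change neighbouring genes. Within 10 Mb of Nfe2l2 16 of 91 tested genes had an unadjusted p under 0.05, against 1642 of 13453 elsewhere. The odds ratio was 1.53 (95% interval 0.833 to 2.67, Fisher's exact p = 0.146), an interval that holds both no excess and a clear one. Of the 16, 8 were higher and 8 lower, and Pdk1 had the lowest p.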
